A study of Mus musculus with 10 samples.

How the data were processed

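Elk1 and Gli2 chromatin immunoprecipitation libraries from mouse cells were analysed at 5 stages, with 1 library each. The series text writes ciNSLC beside day 0, while the labels name day 0 and ciNSLCs as separate samples, and the labels were followed. Per the labels' protocols, chromatin was crosslinked with formaldehyde, sheared and immunoprecipitated, and libraries were amplified by PCR without a stated molecular identifier. Per the submitters' processing notes, CASAVA 1.8.4, FastQC, Bowtie2, SAMtools and genome build mm10 were used, with no role or order given. The peak caller, the measure of signal, the background and the scaling are not given in the sources used here.

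The authors deposited 1 table of loci with a signal value per library, and the signal is never negative. All 10 signal columns were matched to samples by name. Low signals fell on a grid of steps. For each library a step and an offset were fitted to signals below 60 with a tolerance of 0.06, which placed 75.5 to 94.1% of them on the grid. In simulated libraries of 1577 loci the step was recovered within 0.07%. The same background step served both antibodies of a stage, 8.4 at day 0, 7.98 at day 4, 5.9 at day 8, 6.68 in ciNSLCs and 5.2 in pri-NPC. This pattern is what a scaled count less a scaled background count would give, an inference from the values and not a statement of the authors. A signal divided by the step, rounded, was taken as a number of counted units. Total read depth is unknown.

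Signals were compared as deposited, as log2 of the signal plus a pseudocount of 1, which understates differences of low signals. At least 2-fold counted as higher or lower. No test between stages was possible with 1 library per group. A 95% interval of each ratio was computed from counted units with an exact conditional binomial method, chosen after seeing the data, which ignores the background subtraction and covers counting error only. On simulated unchanged loci, 22.2% were called 2-fold higher without the interval and 0.4% with it for Elk1 day 8 against day 0, and 25.5% and 0.7% for Gli2 ciNSLCs against day 0. Loci changed 4-fold were recovered at 95% and 88%, and 8-fold at 100% in both. Because loci were listed for reaching about 100 in some library, a library stands high at the loci listed through it alone. These were 677 for Elk1 pri-NPC, 357 for Gli2 day 0 and 190 for Elk1 day 4, against 2 for Elk1 day 0. Neither the intervals nor the simulations include this listing, so each comparison was also counted over loci that reached 100 in a library other than the pair compared. The medians of 47.6 in Elk1 pri-NPC and 35.8 in Gli2 day 0 set the median scaling and include the loci listed through those libraries. Median scaling draws the numbers of higher and lower loci together by construction, so an even split after it is no evidence on direction.

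Genes came from a RefSeq annotation of GRCm38.p6, the same build as mm10, with 49997 genes. It gives no strand or exons, so distance was taken to either gene end, and exon, intron and UTR are not assigned. Coordinates are printed as in the table, whose count from 0 or 1 is not stated. Each locus was assigned to the nearest protein-coding gene within 50 kb, which gave 964 loci and 697 genes. Mitochondrial tRNA genes were left out of the tRNA class. Random positions were drawn 100 times on the same chromosome, each locus on its own, so clustering of loci was not kept.

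Named genes followed a rule set before the data were examined. It took Sox2, Gli1, Gli2, Gli3, Ptch1 and Elk1 where held, up to 4 members of each of 14 gene lists by the day 8 difference, and, among loci assigned to a gene, the 5 largest increases and decreases at day 8 and in ciNSLCs, leaving out loci with both signals below the 25th percentile of 6.9. Lists of at least 3 genes were set against 10000 random lists. Alternatives fixed beforehand were scaling to the same median, pseudocounts of 0.1 and 5, a filter at the 25th percentile, 1.5-fold and 3-fold limits, the upper 50% of each list, 1 value per gene, the mean over loci of a gene, loci within 5 kb, overlap by region and a 3 kb gap. The 5 kb and gene-end alternatives were planned for start sites and used gene bounds instead. Added after seeing the data were the counting interval, a limit of 150, overlap with the tRNA gene, loci listed through a library other than the pair compared, a test of Gli2 against Elk1 paired by stage, and leaving out loci of Elk1 pri-NPC alone or of both antibodies. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.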

Results

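Chromatin immunoprecipitation with an antibody to Elk1, a transcription factor activated by MAP kinase signalling, or to Gli2, a transcription factor of the Hedgehog pathway, was followed by sequencing at 5 stages. Mouse fibroblasts called tdMEFs in the labels were sampled at days 0, 4 and 8 in M9, a neural medium with small molecules and basic FGF. The other stages were the reprogrammed cells named ciNSLCs and the cells named pri-NPC. There was 1 library per antibody and stage, 10 in all, so no difference below has a replicate check and no p-value is given between stages. The table held 1577 loci with a signal per library, and each locus reached a signal of at least 100.1 in some library. Of these loci, 1271 (80.6%) reached 100 in 1 library only, and 5, all within Sfi1 on chromosome 11, reached it in all 10. The value of 1 counted unit, read from the spacing of low signals, lay between 2.82 in Elk1 ciNSLCs and 14.49 in Elk1 pri-NPC, so a signal of 100 took 36 units in the former library and 7 in the latter. Intervals below come from these units and cover counting error only.

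**Figure D1:**
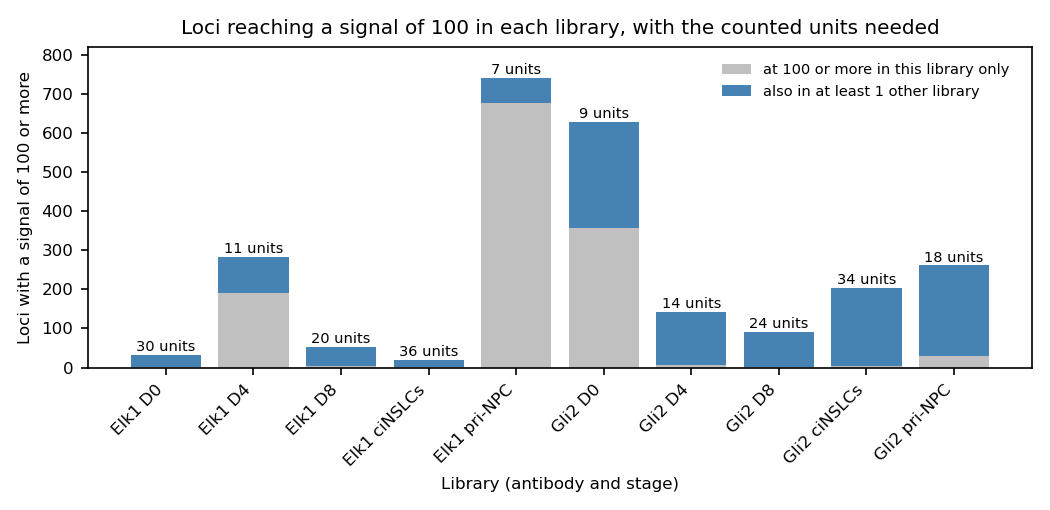
Number of loci with a signal of 100 or more in each of the 10 libraries, split into loci reaching it there only (grey) and loci also reaching it in another library (blue). The number above each bar is the count of units needed to reach 100. Elk1 pri-NPC (741 loci, 677 there only) and Gli2 D0 (628 loci, 357 there only) needed 7 and 9 units.

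The first comparison asked how Elk1 binding differed at days 4 and 8 of reprogramming from day 0. Immediate-early and serum response genes respond to growth factors within minutes. At 4 of 6 loci assigned to such genes, Elk1 signal was higher at both days, beyond counting error. Beside Egr1 (chromosome 18, 34860505 to 34861165, 42 bp from the gene) it was 24 at day 0, 164.7 at day 4 and 137.1 at day 8, a day 4 to day 0 ratio of 6.86 (95% counting interval 2.7 to 19.6). Beside Junb (chromosome 8, 84976465 to 84976845, 64 bp away), a member of the AP-1 family, the signals were 13.7, 203.5 and 100.7, with a day 4 ratio of 14.8 (interval 5 to 59.4). The Fos locus (chromosome 12, 85485865 to 85486385, 8591 bp away) had 37.8, 222.8 and 167.6, and the Egr3 locus (chromosome 14, 70074785 to 70075065, 2252 bp away) had 12.2, 118 and 60.9. The other members were within counting error of day 0. Fosb had Elk1 signals of 3.4, 29.1 and 18.7 (day 4 interval 0.68 to 445). The Spry4 locus, 46702 bp from the gene, had 13.7, 19.4 and 5.1 (day 4 interval 0.13 to 9.86). At a locus overlapping Sox2 (chromosome 3, 34649325 to 34650265), a transcription factor of neural progenitors, Elk1 signal was 29.4 at day 0, 139.1 at day 4 and 55.9 at day 8. The Sox2 ratio was 4.73 at day 4 (interval 1.77 to 11.5) and 1.9 at day 8 (interval 0.68 to 4.93), the latter within counting error. The Sox2 and Egr3 loci reached 100 in the Elk1 day 4 library alone, so they were listed for their day 4 signal, which the intervals ignore, while Egr1, Junb and Fos also reached 100 with Elk1 at day 8 and in pri-NPC. The day 0 library, the base of these ratios, stood apart from the other Elk1 libraries at the 96 loci of both antibodies, with rank correlations of -0.26 to 0.34.

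**Figure D2:**
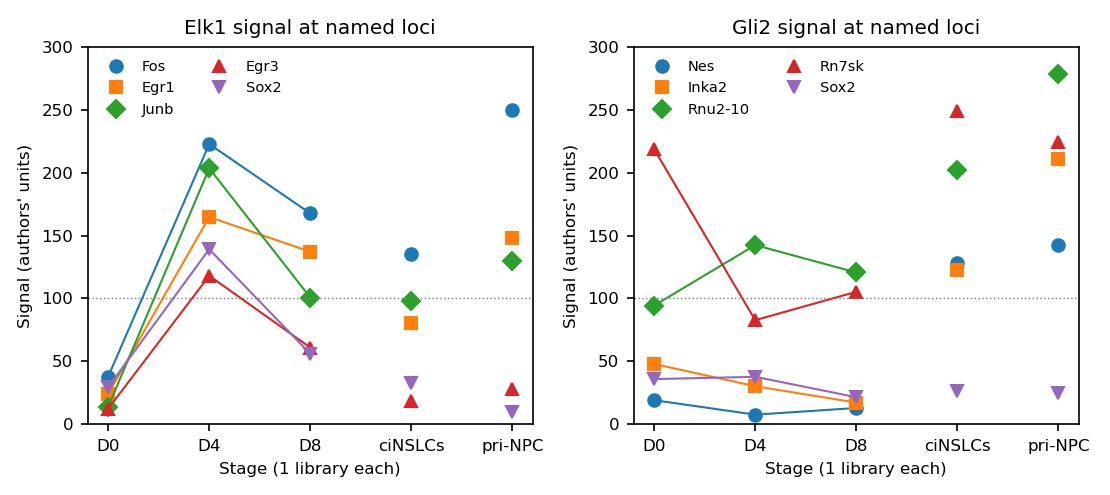
Signal in the authors' units (vertical axis) at named loci in the 5 stages (horizontal axis), for the Elk1 antibody on the left and the Gli2 antibody on the right. Each point is 1 library, lines join days 0, 4 and 8, and the dotted line marks a signal of 100. Elk1 signal at Junb was 13.7 at day 0 and 203.5 at day 4, and Gli2 signal at Nes was 19 at day 0, 128.2 in ciNSLCs and 142.8 in pri-NPC.

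Across all loci, Elk1 signal was at least 2-fold higher at day 4 than at day 0 at 681 loci and lower at 351, and the counting interval left out a ratio of 1 at 278 and 6 of them. Of all loci 190 were listed through Elk1 day 4 alone. Among the 1384 listed through a library other than the pair compared, 500 were higher and 349 lower at day 4, with 105 and 5 beyond counting error. At day 8 the numbers over all loci were 415 higher and 397 lower, with 64 and 27 beyond counting error. Scaling each library to the same median gave 542 higher and 442 lower at day 4. By rule, among loci assigned to a protein-coding gene, the 5 with the largest day 8 increases were those near Rpusd4 (6.9 at day 0, 1231.3 at day 8), in Chl1 (0 and 137.8), near Vmn1r77 (0 and 51.8), near Utp3 (0 and 34.7) and near Agps (0 and 25.4). The largest decreases among such loci were at COX3 on the mitochondrial chromosome (209.6 and 0), near Trpm8 (53.8 and 0) and in Trim50 (52.7 and 0), Cc2d2b (27.5 and 0) and Cdh11 (27.5 and 0), the last pair tied with other loci. The Rpusd4 and Chl1 loci also had high Gli2 signal at day 0, 3382.2 and 480.8. Gli2 signal at COX3 likewise went from 90.7 at day 0 to 0 at day 8.

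Elk1 binding in ciNSLCs and pri-NPC was set against day 0 and against each other. Elk1 signal in ciNSLCs was 80.8 at Egr1, 97.7 at Junb and 135.5 at Fos, with ratios to day 0 of 3.37 (interval 1.46 to 9.21), 7.13 (2.57 to 27.9) and 3.58 (1.84 to 7.66). In pri-NPC the same loci had 148, 129.4 and 249.6. Over these and Egr3 the median log2 difference from day 0 was 1.76 in ciNSLCs and 2.63 in pri-NPC, or 1.78 and 0.42 after median scaling. That of ciNSLCs against pri-NPC was -0.71 and turned to 1.51 after scaling. At Egr3 the signals were 18.7 in ciNSLCs and 27.9 in pri-NPC, and at Sox2 32.8 and 9.3, all within counting error of day 0. The Slc30a4 locus (chromosome 2, 122681225 to 122681585), inside a zinc transporter gene, had Elk1 signals of 5.7 at day 0, 78.4 in ciNSLCs and 174.8 in pri-NPC. That locus was chosen after its values were seen, as 1 of 10 that reached 100 with Elk1 in at least 2 stages and never with Gli2. Gli2 signal there was 64.2 at day 0, 69.4 in ciNSLCs and 89.3 in pri-NPC, so the locus was not free of it.

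In ciNSLCs 355 loci had Elk1 signal at least 2-fold higher than at day 0 and 442 lower, with 46 and 116 beyond counting error. By rule the largest ciNSLC increases at loci assigned to a gene were near Rpusd4 (559.4), in Gpc5 (0 at day 0 and 31), near Olfr809 (0 and 28.2), near BC107364 (0 and 22.6) and near Agps (0 and 22.6). The largest decreases among such loci were at COX3, at 2 loci near Elobl (53.4 and 36.6 at day 0, both 0 in ciNSLCs), in Zfp982 (37.8 and 0) and in Aida (327.9 and 4.6). The Rpusd4 and Aida loci were among those that reached 100 with both antibodies. In pri-NPC 939 loci were higher than at day 0 and 308 lower, and against pri-NPC 228 loci were higher in ciNSLCs and 999 lower. These splits turned when each library was scaled to the same median, to 497 higher and 624 lower for pri-NPC against day 0 and to 536 and 440 for ciNSLCs against pri-NPC. Such scaling draws the split towards even by construction, and the Elk1 pri-NPC median includes the loci listed through that library alone. Without the 677 loci that reached 100 in Elk1 pri-NPC alone, 263 loci were higher and 308 lower in pri-NPC than at day 0. Among loci listed through a library other than the pair compared, 65 were higher and 22 lower in pri-NPC beyond counting error, against 738 and 23 over all loci.

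Gli2 binding over the same days was set against day 0, first at loci beside tRNA genes. A nuclear tRNA gene lay within 1 kb of 208 of the 597 loci that reached 100 with Gli2 only (34.8%, 95% exact binomial interval 31 to 38.8), against 0 of 884 Elk1-only loci (upper limit 0.416%) and 0 of 96 loci of both antibodies (upper limit 3.77%). Of 408 annotated nuclear tRNA genes, 270 had such a locus, and 81 of the loci lay on chromosome 13. The median Gli2 signal at the tRNA loci was 269.9 at day 0, 60.2 at day 4 and 72.3 at day 8, against Elk1 medians between 5.6 and 9.7. The median log2 difference from day 0 was -2.05 at day 4 and -1.96 at day 8. It was -0.80 and -0.48 after scaling each library to the same median, which subtracts -1.25 and -1.48 from the difference at every locus. Gli2 signal was at least 2-fold lower, beyond counting error, at 194 of the 208 loci at day 4 and 192 at day 8. Of the tRNA loci 56 were listed through Gli2 day 0 alone, and among the 152 listed through a library other than the pair compared 140 were lower at day 4 and 136 at day 8. tRNA genes have near-identical copies, so the split of signal between them is uncertain.

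**Figure D3:**
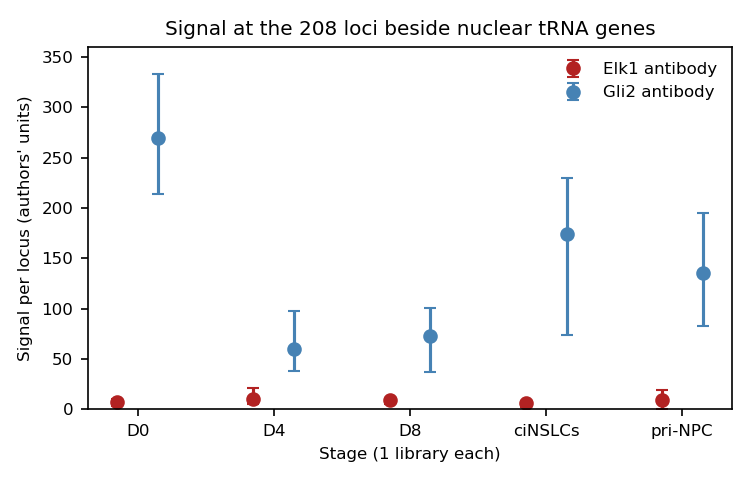
Signal per locus in the authors' units (vertical axis) at the 208 loci within 1 kb of a nuclear tRNA gene, by stage (horizontal axis), for Elk1 (red) and Gli2 (blue). Points are medians over loci in 1 library and bars run from the 25th to the 75th percentile of loci, not over replicates. Gli2 medians were 269.9 at day 0, 60.2 at day 4, 72.3 at day 8, 173.9 in ciNSLCs and 135.6 in pri-NPC, a difference from day 0 that turned upward for ciNSLCs after median scaling.

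Another 32 loci lay beside other small RNA genes, with Gli2 medians of 135 at day 0, 75.2 at day 4 and 72.6 at day 8, and log2 differences of -0.72 and -0.69 that turned to 0.54 and 0.79 after median scaling. Single examples, chosen after their values were seen, were Rn7sk (chromosome 9, 78175125 to 78175805), the 7SK RNA that restrains transcription elongation, with 218.6, 82.7 and 105.2 and a day 8 difference that turned to 0.43 after median scaling, and Rnu2-10 (chromosome 11, 101658285 to 101658745), a U2 spliceosomal RNA gene, with 94.3, 142.4 and 120.6. Over all loci Gli2 signal was at least 2-fold higher at day 4 than at day 0 at 270 and lower at 854, and at day 8 higher at 264 and lower at 899. Beyond counting error these numbers were 9 and 510 at day 4 and 1 and 604 at day 8. Of the 628 loci at 100 with Gli2 at day 0, 357 reached it in no other library. Among loci listed through a library other than the pair compared, 206 were lower beyond counting error at day 4 and 258 at day 8, against 6 and 0 higher. With libraries scaled to the same median, which draws the split towards even by construction, it was 505 higher and 484 lower at day 4 and 501 and 487 at day 8. By rule the largest day 8 increases at loci assigned to a gene were in Gm38510 (0 and 39.3), Cnot1 (0 and 38.4), Atxn3 and Ralgapb (0 and 25.6 each) and near Olfr820 (0 and 25.6), all within counting error. Among such loci the largest decreases, all to 0, were in 2210408I21Rik (142.6), near Clint1 (135), in Tarsl2 (131.4) and Tmeff2 (119.5) and near Olfr339 (119.5). The 2210408I21Rik locus reached 100 with both antibodies. The others reached it in Gli2 day 0 alone, so the listing itself favours their decrease.

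Gli2 binding in ciNSLCs and pri-NPC was set against day 0. At Nes, the gene of the neural stem cell filament nestin, Gli2 signal was higher in both, a result singled out after its values were seen. The locus inside Nes (chromosome 3, 87974205 to 87974645) had Gli2 signals of 19 at day 0, 7.5 at day 4, 12.8 at day 8, 128.2 in ciNSLCs and 142.8 in pri-NPC. Its ratio to day 0 was 6.75 in ciNSLCs (interval 1.41 to 46) and 7.52 in pri-NPC (interval 1.46 to 51.5). The day 0 signal of 19 rests on units worth 11.94 each. Of simulated unchanged loci 0.7% were called higher in ciNSLCs beyond counting error, close to the 12 of 1577 observed. The Inka2 locus (chromosome 3, 105710205 to 105710605), chosen after its values were seen, had 47.8 at day 0, 122.9 in ciNSLCs and 211.2 in pri-NPC, with the ciNSLC ratio of 2.57 (interval 0.93 to 9.9) within counting error. Both were among 7 loci that reached 100 with Gli2 in ciNSLCs and pri-NPC and in no other library. The others lay beside small RNA genes, near or in Tex14, Eapp, Acp6, Kif2c and Sirt4. Gli2 medians at the tRNA loci were 173.9 in ciNSLCs and 135.6 in pri-NPC, median log2 differences from day 0 of -0.78 and -1.01, which became 0.47 and -0.14 after median scaling.

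Over all loci 335 were at least 2-fold higher in Gli2 ciNSLCs than at day 0 and 724 lower, with 12 and 504 beyond counting error. For pri-NPC against day 0 the numbers were 390 and 647, with 34 and 461 beyond counting error. Scaled to the same median they were 582 and 494 for ciNSLCs and 554 and 457 for pri-NPC. Among loci listed through a library other than the pair compared they were 333 and 369 for ciNSLCs, with 10 and 152 beyond counting error. For pri-NPC the split turned, to 365 higher and 295 lower, with 13 and 124 beyond counting error. Against pri-NPC, 237 loci were higher in ciNSLCs and 471 lower, or 338 and 348 after scaling, and 23 and 147 beyond counting error. By rule, again among loci assigned to a gene, the largest ciNSLC increases were near Was (0 at day 0 and 92.9), in Itpr2 (0 and 71.3), Mbnl2 (0 and 36), Tial1 (0 and 32.3) and Olfr292 (0 and 30), of which those in Mbnl2, Tial1 and Olfr292 were within counting error. Among such loci the largest decreases, all to 0, were in Aida (1180.7), Cmss1 (482.9), Lars2 (284.7), near Gm39469 (145.6) and in Zc3h7a (133.6).

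Elk1 and Gli2 were then compared at the same stage, since the heading of the table describes loci bound by both. Over all stages 96 loci (6.09%, exact binomial interval 4.96 to 7.38) reached 100 with both antibodies in any stage, 884 with Elk1 only and 597 with Gli2 only. Within a stage the loci at 100 with both were 28 at day 0, 65 at day 4, 21 at day 8, 17 in ciNSLCs and 50 in pri-NPC. Counted by assigned gene, the shared numbers were 10, 23, 3, 2 and 18. The locus in Smo (chromosome 6, 29748365 to 29748585), the Hedgehog signal transducer, had Elk1 signal of 108.3 at day 4 and Gli2 signal of 123 at day 0, so the 2 antibodies reached 100 at different stages. Of the 96 loci, 18 lay on chromosome 11 between 3126945 and 3200085 and 16 on chromosome 9 between 2999865 and 3038365. The highest signals of all were on chromosome 2 between 98666085 and 98667465, with 7140 for Elk1 in pri-NPC, 6966.8 for Elk1 at day 4 and 6670.2 for Gli2 at day 0. No test of overlap was made because the table gives no background of loci that could have been listed.

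Gene lists fixed beforehand were compared by the nearest protein-coding gene within 50 kb. Of 45 annotated immediate-early and serum response genes, 6 had a locus. Egr1, Egr3, Fos and Junb reached 100 with Elk1, and Fosb and Spry4 with Gli2. The median log2 Elk1 difference of the 6 from day 0 was 2.75 at day 4, 2.2 at day 8, 1.14 in ciNSLCs and 1.85 in pri-NPC, the last turning to -0.36 after median scaling. Among 10000 random lists matched on mean level, drawn from genes listed through any library, these medians lay at percentiles 99.0, 100.0, 99.3 and 86.3. Over loci listed through a library other than the pair compared, which leaves out Egr3 at day 4, the percentiles were 98.9, 99.9, 99.4 and 91.6. Their median Gli2 differences were -1.95, -2.78, -2.19 and -2.75, at percentiles 18.2, 4.5, 10.9 and 3.2, or 2.3, 1.0, 5.0 and 1.1 over loci listed elsewhere, which leaves out Spry4. After median scaling these Gli2 medians were -0.69, -1.29, -0.93 and -1.88. Of the Egr1, Egr3, Fos and Junb loci, 0, 1, 1 and 1 were at least 2-fold lower with Gli2 beyond counting error. Their day 0 Gli2 signals were 23.9 to 63.3, with a unit worth 11.94. Fosb and Spry4 were both lower beyond counting error at day 8. The Fosb difference turned to 0.08 after median scaling. Spry4 was listed through Gli2 day 0 alone, which favours its decrease. Of 61 neural progenitor genes 5 had a locus. Sox2 reached 100 with Elk1, and Nes, Msi2, Pax6 and Slc1a3 with Gli2. Msi2, Pax6 and Slc1a3 did so at day 0 alone, with 119.5, 107.5 and 107.5. The list's median Gli2 difference was -1.64 at day 4, -2.39 at day 8, -2.3 in ciNSLCs and -2.54 in pri-NPC, at percentiles 98.7, 93.8, 96.4 and 82.9, with too few members listed elsewhere to repeat it. After median scaling the Gli2 medians were -0.39, -0.91, -1.05 and -1.68. Nes was the 1 member at least 2-fold higher in ciNSLCs and in pri-NPC. The list's median Elk1 differences were -1.22, -0.13, -1.01 and -1.56, at percentiles 7.9, 39.2, 25.6 and 16.9.

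Of 50 fibroblast genes 3 had a locus, Thbs1 and Zeb2 with Gli2 at day 0 (123 and 107.5) and Fap with Elk1 in pri-NPC (101.6). In the same order of stages their median Gli2 differences were -2.8, -2.78, -3.06 and -3.92, at percentiles 28.5, 53.4, 39.7 and 9.4, and their Elk1 ones -0.55, 0.47, -0.94 and -2.14, at percentiles 28.7, 62.5, 32.6 and 21.4. After median scaling the Gli2 medians were -1.54, -1.29, -1.81 and -3.05, and the Elk1 pri-NPC median was -4.35. Thbs1 and Zeb2 were listed through Gli2 day 0 alone, which favours their decrease. Too few members were listed elsewhere to repeat the Gli2 comparison, so its medians and percentiles cannot show a decrease apart from the listing. Of 63 ribosomal, translation and mitochondrial genes 4 had a locus. Cox5a and Eef2 had Gli2 signals of 111.1 and 155.3 at day 0, Polg had 227 beside a tRNA gene, and Ndufb5 had an Elk1 signal of 106.6 at day 4. Their median Gli2 differences were -2.2, -2.28, -2.11 and -3.67, at percentiles 17.3, 28.8, 21.5 and 1.1, and their Elk1 ones 0.55, 0.18, -0.49 and -3.16, at percentiles 53.9, 59.1, 41.8 and 1.5. After median scaling the Gli2 medians were -0.95, -0.8, -0.86 and -2.8, and the Elk1 pri-NPC median was -5.37. Cox5a and Eef2 were likewise listed through Gli2 day 0 alone, with too few members listed elsewhere to repeat the Gli2 comparison. The same limit therefore holds for the Gli2 medians and percentiles of this list. Without Ndufb5, listed through Elk1 day 4 alone, the Elk1 day 4 median turned to -1.22, at percentile 13.0. Smaller lists had Smo and Sox2 (Hedgehog), Aurkb and Mcm3 (cell cycle), Prdm14 and Sox2 (pluripotency), Slc17a6 (neuronal), Spry4 (FGF and MAPK), Nog (TGF-beta and BMP), Tcf7l1 (Wnt) and Myf5 (other lineages). With loci within 5 kb only, the FGF and MAPK, TGF-beta and BMP and other-lineage lists had 0 genes. The cell cycle and pluripotency lists then had 1 each, and the immediate-early and neural progenitor lists 4 each. The Aurkb locus (chromosome 11, 69040245 to 69042225) lay beside a tRNA gene and had Gli2 signals of 500.4 at day 0, 255.7 at day 4 and 224.8 at day 8, a log2 difference that turned to 0.33 at day 8 after median scaling. Elk1 signal at Tcf7l1 was 13.7 at day 0 and 127.7 at day 4, and at Myf5 12.2 and 129.4, both listed through Elk1 day 4 alone. Of the retinoic acid list 0 of 30 genes had a locus, and of the chromatin list 0 of 39. Gli1, Gli2, Gli3, Ptch1 and Elk1 had no locus assigned to them, so their signal as target genes was not compared. Of the 44 Hedgehog genes 2 had a locus, Smo and Sox2, and Gli2 signal at Sox2 did not exceed 37.6.

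The position of loci was measured as the gap to either end of a protein-coding gene. Within 1 kb lay 7.1% of all loci, 3.85% of Elk1-only loci and 12.7% of Gli2-only loci. Randomly placed loci of the same widths averaged 3.54%, 3.46% and 3.59%. Of the 884 Elk1-only loci 677 were of Elk1 pri-NPC alone, with 2.51%. The 190 of Elk1 day 4 alone had 6.32%, level with the upper end of the central 95% of random placements, and 16.8% within 3 kb, against an upper end of 12.4%. Of the 10 loci at 100 with Elk1 in at least 2 stages and never with Gli2, 30% lay within 1 kb and 60% within 3 kb, against upper ends of 20% and 30%. Several of the 10 lay close together in Gm38510 (chromosome 1, 85277625 to 85281385). Random placements moved each locus on its own, so these upper ends may be too low. Gli2 signal at some of these 10 loci came close to 100, up to 94.6, so the set is not free of Gli2 signal. Gli2-only loci without a tRNA or other small RNA gene had 6.7%, against a mean of 3.5% at random and 5.45% at the upper end of the central 95% of random placements. Loci of both antibodies had 2.08%, against 5.55% at random.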

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

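The counting interval, the limit of 150, overlap with the tRNA gene, listing through another library, the test paired by stage and the removal of loci were chosen after seeing the data. Between stages, no paired analysis was possible because each group had 1 library. Gli2 against Elk1 was paired by stage over 5 pairs, where an exact two-sided sign-flip permutation p cannot go below 0.0625. The median at tRNA loci, all of them listed through Gli2, was higher with Gli2 in 5 of 5 pairs, by a mean of 3.78 on the log2 scale (SD 1.13, exact permutation p = 0.0625). The number of loci at 100 was higher with Gli2 in 3 of 5 (exact permutation p = 0.75). Of the summary values, 161 alternatives stayed within 1.5 times or within their interval and 114 did not. Of the named loci and lists, 2072 stayed, 136 moved and 17 reversed, where reversed means that a value at least 2-fold and beyond counting error, or the median of a list, changed sign. One was the ribosomal, translation and mitochondrial list, whose Elk1 day 4 median became -1.22 over loci listed through a library other than the pair compared. Median scaling of list medians was not among the alternatives counted, so the immediate-early Elk1 pri-NPC median, which turned to -0.36, is not included. At named loci 106 log2 values changed sign, of which 16 had met both criteria and 90 had not. Pseudocounts of 0.1 and 5 left each count of loci within 1.5 times, and so did leaving out the loci of both antibodies. Counts below are in the order day 4, day 8, ciNSLCs and pri-NPC against day 0, then ciNSLCs against pri-NPC. The reported counts were 681, 415, 355, 939 and 228 higher and 351, 397, 442, 308 and 999 lower for Elk1, and 270, 264, 335, 390 and 237 higher and 854, 899, 724, 647 and 471 lower for Gli2. With 1 value per gene, where fewer units are counted by construction, Elk1 had 324, 165, 124, 374 and 107 higher and 137, 169, 195, 158 and 403 lower, and Gli2 102, 102, 109, 140 and 112 higher and 408, 429, 332, 310 and 182 lower. In the upper 50% of the loci of each antibody, also fewer by construction, Elk1 had 309, 153, 130, 316 and 61 higher and 79, 108, 120, 90 and 333 lower, and Gli2 7, 3, 14, 19 and 20 higher and 274, 296, 179, 169 and 79 lower. With a counting interval that left out 1, Elk1 had 278, 64, 46, 738 and 2 higher and 6, 27, 116, 23 and 744 lower, and Gli2 9, 1, 12, 34 and 23 higher and 510, 604, 504, 461 and 147 lower. That interval removes loci with few counted units by construction. With a mean at or above the 25th percentile, Elk1 had 289 lower in ciNSLCs, 154 lower in pri-NPC and 108 higher in ciNSLCs against pri-NPC, and Gli2 had 159, 122, 159 and 199 higher against day 0. At 1.5-fold, Gli2 had 357 higher in ciNSLCs against pri-NPC, and at 3-fold 156 higher and 300 lower, while Elk1 had 286 lower in ciNSLCs against day 0. Without the loci of Elk1 pri-NPC alone, Elk1 had 158 lower at day 4, 221 higher and 212 lower at day 8, 145 higher in ciNSLCs, 263 higher in pri-NPC and 323 lower in ciNSLCs against pri-NPC. Gli2 then had 71, 52, 74, 84 and 150 higher and, in ciNSLCs against pri-NPC, 235 lower, and 207 in place of 884 loci were Elk1 only.

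Over loci listed through a library other than the pair compared, Elk1 had 263 higher in pri-NPC and 323 lower in ciNSLCs against pri-NPC, and Gli2 504, 546, 369 and 295 lower against day 0, since this leaves out loci listed for 1 of the pair.

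Scaling each library to the same median gave Elk1 497 higher and 624 lower for pri-NPC against day 0 and 536 and 440 for ciNSLCs against pri-NPC, and Gli2 505 and 484 at day 4, 501 and 487 at day 8 and 582 higher in ciNSLCs. It subtracts 0.52, -0.01, -0.01, 2.21 and -2.22 from the log2 differences of Elk1 and -1.25, -1.48, -1.25, -0.87 and -0.39 from those of Gli2. All 106 sign changes at named loci came from it. For Elk1 pri-NPC against day 0 the log2 values became -0.64 at Gm38510, -1.19 at Aida, -0.49 at Elobl and -0.14 at Tial1. For Gli2 day 4 against day 0 they became 0.17 at Cmss1, 0.17 at the chromosome 2 locus from 98662085 to 98663105, 0.01 at Rny3, 0.13 at Polg and 0.11 at Rpusd4. For Gli2 day 8 they became 0.33 at Aurkb, 0.01 at Cmss1, 0.08 at Fosb, 0.11 at Rmrp, 0.43 at Rn7sk and 0.27 at a locus in Sfi1, and for Gli2 ciNSLCs 0.14 at another locus in Sfi1. With a limit of 150 in place of 100, 23 loci were Elk1 only, 248 Gli2 only and 60 of both. Within 3 kb of a gene end lay 13.7% of all loci, 8.82% of Elk1 only, 21.8% of Gli2 only and 8.33% of both. Overlap of the antibodies counted by region gave 28, 65, 21, 17 and 50 for the 5 stages, and the same numbers at 50% of the shorter region since shared loci are the same intervals. In the upper 50% of each list the shared genes were 3 at day 0, 1 in ciNSLCs and 9 in pri-NPC. For the other moved values the cause was not tested. A counted unit was worth most in Elk1 pri-NPC, 14.49, so a given signal there rests on the fewest units. Sequencing depth itself was not measured.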

Other observations

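All tests below were chosen after the result was seen, except the gene-end test of Elk1 pri-NPC and the correlation test of the loci of both antibodies over all stages. The ratio of the Gli2 median at loci beside other small RNA genes to that at tRNA loci was 0.5 at day 0, 1.25 at day 4, 1 at day 8, 0.9 in ciNSLCs and 0.94 in pri-NPC, a difference not tested, with the low value in 1 library. Genes chosen after their values were seen included Rny1, a Y RNA gene, with Gli2 signals of 242.5 at day 0, 22.1 at day 4, 139.3 at day 8, 270.7 in ciNSLCs and 202.1 in pri-NPC. Rnu11, the U11 RNA of the minor spliceosome, had 114.6, 127.8, 98.2, 203.2 and 299.9. The RNA of RNase MRP, Rmrp, had 155.3, 75.2, 59.8, 169.5 and 183.8, and Rny3 had 213.7, 90.2, 67.7, 179.2 and 112.1. Median scaling turned several negative differences from day 0 at these genes upward, among them Rmrp at day 4 (0.21) and day 8 (0.11) and Rny3 at day 4 (0.01) and in ciNSLCs (0.99). The Malat1 locus, a long nuclear RNA gene, had 97.8, 195.5, 68.3, 128.9 and 141.5.

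Of the 200 loci that reached 100 with Gli2 in at least 2 stages and never with Elk1, 151 lay beside a tRNA gene (75.5%, exact binomial interval 68.9 to 81.3) and 26 beside another small RNA gene. Signal that does not depend on the antibody is argued against, since the mean Elk1 median at tRNA loci was 0.057 of the Gli2 one. Gli2 itself at these genes, and another protein bound by the Gli2 antibody, cannot be told apart, because 0 libraries came from cells without Gli2. Either may account for the signal.

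Loci that reached 100 in 1 library only were most frequent where few counted units sufficed, and over the 10 libraries Spearman's rho between the units needed and the number of such loci was -0.92 (permutation p = 0.00028, adjusted 0.00056) and Pearson's r was -0.70 (permutation p = 0.011, adjusted 0.011), with 2 relations computed. Without both ciNSLC libraries, the farthest in units, r was -0.75. Elk1 binding close to gene ends is argued against for the Elk1 pri-NPC loci alone, as 2.51% lay within 1 kb of one against 3.27% at random. Counting noise may account for many of these, and 299 of the 741 loci at 100 in Elk1 pri-NPC had the same signal of 101.6, close to 7 units, with binding away from gene ends left open. For other libraries binding near gene ends stays open, with 5.6% of the loci of Gli2 day 0 alone within 1 kb (random upper end 5.19) and 15.4% within 3 kb (10.6), and 16.8% of those of Elk1 day 4 alone within 3 kb (12.4).

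The 96 loci of both antibodies clustered, 59 lying within 100 kb of another. Their mean rank correlation between the antibodies within a stage exceeded that of 1 antibody between stages by 0.2 (0.66 against 0.46). At all other loci the within-stage mean was 0.08, but these reached 100 with 1 antibody and never the other, which lowers it by construction. Without day 0 the excess at the 96 loci was 0.27, and signal that does not depend on the antibody may account for these loci at the other 4 stages. The 96 loci were chosen for reaching 100 with both antibodies. The background step shared by both antibodies of a stage could itself raise their within-stage correlation, which was not tested. At day 0 the correlation was 0.02, a difference of -0.44 from the between-stage mean (95% interval -0.63 to -0.04 over resampled clusters, added to the criterion after the value was seen, without which the test would have argued against that explanation at day 0), and Gli2 signal was at least 4-fold above Elk1 at 44 loci and the reverse at 0. Elk1 day 0 also correlated at -0.26 to 0.34 with the other Elk1 libraries, and Gli2 day 0 at 0.34 to 0.7 with the other Gli2 libraries, so a property of the Elk1 day 0 library and dependence on the antibody cannot be told apart there. Of the loci of both antibodies 2.08% lay within 1 kb of a gene end, below the random upper end of 10.96%, so no excess there was seen. With 96 clustered loci and an exact interval of 0.253 to 7.32%, which holds the random mean of 5.55%, this test cannot decide on separate binding of both proteins close to gene ends. That explanation and a stage effect common to both antibodies stay open.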
